A study of Rattus norvegicus with 18 samples.

How the data were processed

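RNA was measured in the left hippocampus of adult male Sprague-Dawley rats from 2 models of acquired epilepsy, kainic acid (KA) and electrical kindling (KI). Per the labels' protocols, total RNA was extracted from flash-frozen tissue, libraries were built with the NEBNext Ultra II RNA kit, and single-end reads of 110 bases were sequenced on a NovaSeq instrument. The labels give the molecule as polyadenylated RNA. The deposited table holds raw counts of reads per gene symbol, 1 column per library, with no normalization. Per the submitters' processing notes, FastQC, Trimmomatic, HISAT2, featureCounts and DESeq2 were used with the rat genome build rn6; versions are not given there. The annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads shared between near-identical genes, such as the RT1 genes of the rat major histocompatibility complex, or between overlapping genes may therefore have been split or dropped.

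Each of the 18 columns was matched to a sample by the library name in the labels, and 0 columns were left unmatched. Groups and replicate numbers came from the sample titles: KA sham (n = 7), KA 3 Class V (n = 3), KI sham (n = 4) and KI 3 Class V (n = 4). The labels speak of hippocampi from each animal but do not state for every library that it is a separate animal. If some are not, the p-values measure a spread that is partly technical. Total counts per library ran from 30925368 to 49943021. The table lists 17455 gene symbols, of which 1846 had 0 counts in all 18 libraries. Against a reference list for the rat assembly GRCr8, used for names and for no coordinates, 15501 symbols matched, 1606 matched a synonym and 348 had no match. All 36 pairs of libraries within a group differed by far more than counting error (chi-square per degree of freedom 20.4 to 602.6), so each library was kept as its own replicate.

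Differential expression was tested in R 4.3.3 with edgeR 4.0.16, using TMM factors, the filterByExpr filter (13338 genes kept), group means as the design and the robust quasi-likelihood F test. All 18 libraries entered 1 fit, which left 14 residual degrees of freedom. Each test was two-sided with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The contrasts were 3 Class V against sham within each model, the KA change minus the KI change, and KA sham against KI sham. The models have separate shams, so their fold changes share no control library. A standard error is the absolute log2 fold change divided by the square root of F. Levels are given as CPM, counts scaled by library size and TMM factor, as mean ± SD, and log2 CPM used a prior count of 2.

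Before the data were examined, 27 gene lists with 457 entries were fixed, covering cell types, inflammation, activity-dependent genes, synaptic and channel genes, stress, metabolism and tissue from outside the hippocampus. Of the entries, 439 were in the table and 431 passed the filter. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 27 lists of a comparison, and again with an estimated correlation and with fry. Members were also counted as called over all genes and as called when adjusted over the list alone. The rule for named genes was fixed at the same time. It takes the 8 genes with the largest rise and the 8 with the largest fall in each model that are called, have a mean log2 CPM of at least 1, carry a regular symbol and separate every 3 Class V library from every sham. It adds up to 3 members of each list with the smallest p and the genes called in both models in the same direction. It also adds the 5 largest differences between models each way and the largest differences between the shams. Genes named outside it are marked as chosen after their values were seen.

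The procedure was tested on simulated counts with 200 genes changed. For KA, 26.9%, 73.1% and 90.9% of genes changed by 1.5-fold, 2-fold and 4-fold were recovered, with 6 false calls among 13299 genes. For KI these shares were 17.9%, 65.2% and 93.9%, with 4 false calls among 13296 genes. The simulated genes varied independently of each other. In the real libraries genes moved together, with an estimated correlation of up to 0.86 within a list (choroid plexus markers). The shares and false calls may therefore not carry over to the real data. A list score is the mean, over the list's members, of log2 CPM minus the gene's mean over all libraries. The same score over 88 genes whose symbols start with Rpl or Rps and a digit was used to describe libraries and as a covariate. They are called ribosomal protein genes below, though the pattern also matches some other genes, such as kinases named after a ribosomal protein.

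Alternatives set before the data were examined were DESeq2 1.42.0, limma-voom with quality weights, RLE and upper quartile factors, no filter and a filter of 1 CPM in 7 libraries, each model fitted alone, leaving out each library, the replicate number as a block, 1 surrogate variable from sva 3.50.0, and a threshold of 0.1. Alternatives added after seeing the data left out libraries rich in ribosomal RNA-like reads, libraries rich in choroid plexus transcripts or KI sham 3 and 4, removed ribosomal RNA-like genes, or added the ribosomal protein covariate, with and without KA sham 1. Counts of calls were compared with those from up to 100 other splits of the libraries. Results for some genes that the rule names are not reported here. The bisulfite sequencing that the design text mentions was not analysed here.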

Results

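Gene expression was measured by sequencing polyadenylated RNA from the left hippocampus of adult male Sprague-Dawley rats in 2 models of temporal lobe epilepsy. In the kainic acid (KA) model, repeated systemic doses of kainic acid, an agonist of a class of glutamate receptors, brought on status epilepticus. In the kindling (KI) model, rats received repeated electrical stimulation through electrodes in the hippocampus until seizures were established. Tissue was collected 24 hours after the last seizure. Each model had sham controls and a group labelled 3 Class V, a name that the sources used here do not explain further for either model. There were 7 KA sham, 3 KA 3 Class V, 4 KI sham and 4 KI 3 Class V libraries. Total counts ran from 32150130 to 42619628 in the KA shams, from 37172455 to 49943021 in KA 3 Class V, from 30925368 to 38850420 in the KI shams and from 36117956 to 41195373 in KI 3 Class V. Of the genes listed, 13338 were expressed highly enough to be tested. The comparisons ask what changed in each model, which changes the models share, as the series title frames it, and where they differ.

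Several libraries stood apart from the others of their group. The first principal component of log2 CPM held 34.9% of the variance and the second 20.6%. The mean correlation between libraries of a group was 0.993 in KI 3 Class V, 0.987 in KA 3 Class V, 0.980 in the KA shams and 0.962 in the KI shams. KA sham 1 was closer to the KI 3 Class V libraries (mean r = 0.993 across genes, which are not independent replicates) than to the other KA shams (mean r = 0.978). Ribosomal RNA-like genes took 16.6% of the counts in KI 3 Class V 1, 16.7% in KI sham 2 and 9.81% in KA sham 4, against 0.574% to 2.04% in the other 15 libraries. This class was drawn up after the data were seen and holds 7 genes. Of these 2, LOC310926 and LOC257642, match no gene of the reference and were included because they follow the 5.8S gene Rn5-8s across libraries (r = 0.981 and 0.976). These 2 unidentified genes took 15.4%, 14.9% and 8.98% of the counts in those 3 libraries. Ttr, the transthyretin made by the choroid plexus, stood at 887 CPM in KI sham 4 and 572 CPM in KA sham 3, and at 4.13 to 63.8 CPM in the rest. Spp1, the osteopontin of activated microglia and macrophages, stood at 373 CPM in KI sham 3 and 249 CPM in KI sham 4, against 3.46 and 46.3 CPM in KI sham 1 and 2. The mean score of 88 ribosomal protein genes was 0.09 ± 0.54 in the KA shams, −0.03 ± 0.11 in KA 3 Class V, 0.25 ± 0.44 in the KI shams and −0.38 ± 0.13 in KI 3 Class V (log2, SD).

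In the KA model, genes of antigen presentation and of reactive astrocytes were higher 24 hours after the last seizure. Cd74, the invariant chain of class II histocompatibility molecules, rose from 51.4 ± 31.7 CPM in the shams (SD, n = 7) to 426 ± 78.7 CPM in KA 3 Class V (SD, n = 3). The class II chains RT1-Ba and RT1-Db1 rose from 4.50 ± 2.73 to 37.2 ± 8.25 CPM and from 4.61 ± 2.14 to 30.5 ± 5.23 CPM. Gfap, the intermediate filament of astrocytes, rose from 3576 ± 1201 to 8446 ± 963 CPM, and Fos, an activity-dependent transcription factor, from 7.06 ± 1.11 to 17.9 ± 3.83 CPM. In log2 units the rise was 3.05 ± 0.36 for Cd74 (SE, edgeR adjusted p = 0.000784), 3.05 ± 0.37 for RT1-Ba (edgeR adjusted p = 0.000868) and 2.73 ± 0.28 for RT1-Db1 (edgeR adjusted p = 0.000186). The other genes with the largest rises were RT1-Da (2.53 ± 0.46), the sodium channel gene Scn7a (2.46 ± 0.44), the small heat shock protein Hspb1 (2.11 ± 0.34), the asparaginase Aspg (1.98 ± 0.26) and the complement inhibitor Serping1 (1.76 ± 0.33), with edgeR adjusted p from 0.00182 to 0.0312. RT1 genes are close paralogs, and how shared reads were counted is not known, so the value of any single RT1 gene is uncertain. Trh, which encodes thyrotropin-releasing hormone, rose by 4.75 ± 0.87 in log2 (edgeR adjusted p = 0.0281). Its level was 28.4, 19.4 and 386 CPM in the KA 3 Class V libraries, 0.994 to 4.63 CPM in 6 KA shams and 23.7 CPM in KA sham 1. The log2 change of Trh was 5.96 without KA sham 1. Without KA 3 Class V 3 it was 2.14, that of Scn7a 1.76 and that of Hspb1 1.43, and these 3 were not called.

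Across all genes, edgeR called 23 higher and 0 lower in KA 3 Class V, with a median fold of 3.94. At an unadjusted p under 0.05 there were 846 genes up and 479 down. DESeq2 called 254 genes, 187 of them up, and limma-voom called 725, of which 476 were up. In 22 of the 23 genes every KA 3 Class V library lay above every KA sham, and the exception was Trh. Without KA 3 Class V 3, 9 genes were called, each of them among the 23, including Cd74, RT1-Ba, RT1-Db1, RT1-Db2, Aspg, Fos, S1pr3 and Lrrc8e. RT1-Db2, Lrrc8e, Gfap, C3 and Ciita were named after their values were seen. The count was also 14 without KA sham 7, 15 without KA sham 3, 54 without KA 3 Class V 1 or KA sham 1, 62 without KA sham 4, 110 without KI sham 1, 35 without KI sham 3, 42 without KI sham 4 and 69 without both of these, and it was 205 with the ribosomal protein score as a covariate.

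**Figure D1:**
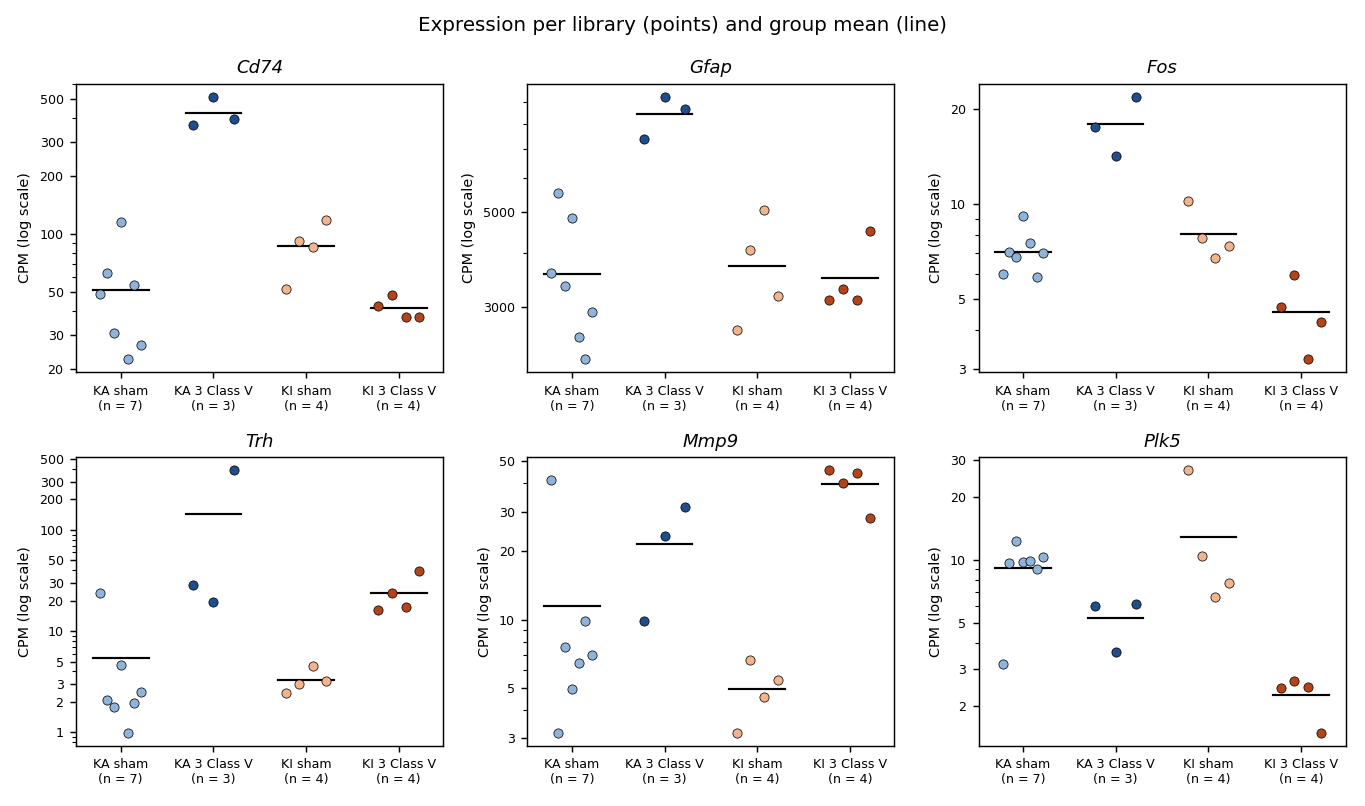
CPM on a log axis of 6 genes in each library (points) with the group mean (line), by group. Cd74, Gfap and Fos were higher in the 3 KA 3 Class V libraries than in any KA sham, while KA sham 1 lay at 23.7 CPM of Trh, 41.4 CPM of Mmp9 and 3.18 CPM of Plk5, near the KI 3 Class V libraries.

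Among the 27 gene lists, complement and antigen presentation genes had the smallest camera p in KA, with a mean of 1.30 (0.85 without KA 3 Class V 2 and 0.74 without KA 3 Class V 3). Of the 19 measured members of that list, 6 rose (Cd74, RT1-Ba, RT1-Db1, RT1-Da, Serping1 and C3) and 13 did not pass, while 12 rose when adjusted over the list alone. The camera adjusted p was 5.81e-21, and adjusted p = 0.124 with an estimated correlation. By fry this list and reactive astrocyte genes passed (adjusted p = 0.00933 for each), as did immediate early genes (0.0478). All 20 reactive astrocyte genes had positive fold changes. Of these, 4 rose (Aspg, Hspb1, Gfap and the sphingosine phosphate receptor S1pr3 at 1.60 ± 0.20), and 14 did so when adjusted over the list alone (camera adjusted p = 9.77e-16, and adjusted p = 0.124 with an estimated correlation). Among 18 immediate early genes, whose transcription follows neuronal activity, Fos (1.34 ± 0.18) and Egr2 (1.55 ± 0.30) rose, 16 did not pass, and 3 rose when adjusted over the list alone (camera adjusted p = 0.000173, and adjusted p = 0.230 with an estimated correlation). Of 19 neuropeptide and neurotrophic genes, Trh rose. When adjusted over the list alone 4 were up and 1 down, and camera did not call the list (adjusted p = 0.153). Without KA sham 1 or KA 3 Class V 2 camera did call it (0.0255 and 0.0141). Npy was at 113, 194 and 877 CPM in the KA 3 Class V libraries, and Inhba at 2.34, 2.39 and 20.5 CPM. Neither was called (edgeR adjusted p = 0.214 and 0.101), and without KA 3 Class V 3 their log2 changes were 0.25 and 0.18. Without KA 3 Class V 3 the call ended for Trh, Egr2, Gfap, C3, Serping1, RT1-Da, Scn7a and Hspb1 (edgeR adjusted p = 0.647, 0.342, 0.301, 0.300, 0.323, 0.234, 0.367 and 0.252), and the fold of Trh was 4.40 in place of 26.9 (62.3 without KA sham 1). RT1-Da was also lost without KA 3 Class V 2 or KA sham 3, 5, 6 or 7, Scn7a without KA sham 3 or 7, and Trh without KA sham 3, 5, 6 or 7 (edgeR adjusted p up to 0.0881). Serping1 was lost without KA 3 Class V 2, KA sham 3, 5, 6 or 7, or KI 3 Class V 2 or 3 (up to 0.0895). C3 was lost without KA 3 Class V 2, KA sham 2, 3, 5 or 7, KI 3 Class V 2 or 3, or KI sham 2 (up to 0.102). Egr2 was lost without KA 3 Class V 1 or 2, KA sham 2, 3, 5 or 7, or KI 3 Class V 3 (up to 0.0957). Gfap was lost without any 3 Class V library of either model, KA sham 1, 3, 5, 6 or 7, or KI sham 2 (up to 0.145 besides KA 3 Class V 3).

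Camera at the preset correlation also called glial and inflammatory lists without a single called member in KA. By fry only the stress list among them passed (fry adjusted p = 0.0478), and the others lay at 0.155 to 0.481. Microglia markers were higher by a mean of 0.53 in log2. Of the 17, 0 passed over all genes, 5 rose when adjusted over the list alone, and Itgam stood at 1.61 ± 0.37 (camera adjusted p = 2.42e-07, and adjusted p = 0.336 with an estimated correlation). Cytokines and chemokines were higher by a mean of 0.83, with 0 of 19 passing and 3 rising when adjusted over the list alone (camera adjusted p = 7.89e-06, and adjusted p = 0.379 with an estimated correlation). Activated microglia and macrophage genes were higher by a mean of 0.58, with 0 of 18 by either count (camera adjusted p = 5.77e-05, and adjusted p = 0.379 with an estimated correlation). Heat shock and stress genes were higher by 0.30, with 0 of 18 passing and 1 when adjusted over the list alone (camera adjusted p = 0.000884, and adjusted p = 0.162 with an estimated correlation). Extracellular matrix genes were higher by 0.48, with 0 of 19 passing and, adjusted over the list alone, 4 up and 1 down (camera adjusted p = 0.0127, and adjusted p = 0.631 with an estimated correlation). Astrocyte markers were higher by 0.12, with 0 of 15 passing and 4 when adjusted over the list alone (camera adjusted p = 0.0399, and adjusted p = 0.581 with an estimated correlation). Without KA 3 Class V 3 the mean was 0.24 for cytokines, 0.26 for activated microglia genes, 0.097 for stress genes and 0.089 for matrix genes. That of immediate early genes was then 0.17 in place of 0.44. The camera adjusted p was then 0.0526 for immediate early genes, 0.0609 for stress genes and 0.310 for matrix genes, and the matrix list was also lost without KA sham 2 (0.0526) or with 1 surrogate variable (0.410). The astrocyte marker list was lost without KA 3 Class V 1 (0.0872) or 2 (0.0586), KA sham 1 (0.115) or 6 (0.226, mean 0.070), KI sham 3 (0.0515), or KI sham 3 and 4 (0.0743).

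Lists that camera called lower in KA at the preset correlation were oligodendrocyte, pyramidal cell, blood, cholesterol and respiratory chain genes. By fry only the pyramidal cell list among them passed (fry adjusted p = 0.0478), and the others lay at 0.155 to 0.485. Myelin and oligodendrocyte markers were lower by a mean log2 change of −0.43, with 14 of 15 negative and Mbp at −0.94 ± 0.28. Over all genes 0 passed and 4 fell when adjusted over the list alone (camera adjusted p = 3.10e-06, and adjusted p = 0.336 with an estimated correlation). All 12 pyramidal cell markers of the CA fields had negative fold changes (mean −0.35), of which 0 passed and 1 fell when adjusted over the list alone (camera adjusted p = 0.000499, and adjusted p = 0.162 with an estimated correlation). The 28 complex I subunits had a mean of −0.36, with 0 called by either count (camera adjusted p = 4.15e-05, and adjusted p = 0.631 with an estimated correlation). Blood cell genes had a mean of −1.38, with 0 of 8 passing and 6 falling when adjusted over the list alone (camera adjusted p = 0.000939, and adjusted p = 0.419 with an estimated correlation). Cholesterol biosynthesis genes had a mean of −0.15, with 0 of 19 by either count (camera adjusted p = 0.00336, and adjusted p = 0.379 with an estimated correlation), and the list was at −0.094 and not called without KA 3 Class V 2 (0.110). Without KA sham 2 the mean was −0.22 for complex I and −0.91 for blood cell genes. With the ribosomal protein covariate complex I was at −0.20. With 1 surrogate variable it was at −0.064, and blood cell genes were at −0.77 and not called (camera adjusted p = 0.0516). The 12 remaining lists besides neuropeptides were not called in KA, with camera adjusted p from 0.0871 for endothelial and pericyte markers to 0.930 for dentate granule cell markers. The endothelial list was called without KA 3 Class V 2 (0.0141), KA sham 3 (0.0158) or KA sham 5 (0.00737). With 1 surrogate variable camera also called voltage-gated channels (0.000417), interneuron markers (0.0498) and choroid plexus markers (0.0373), all lower. Between these 2 lists were voltage-gated channels (0.650), glutamate receptors (0.902), GABA receptors (0.848), interneuron markers (0.517), choroid plexus markers (0.370) and oligodendrocyte precursors (0.517). The others were immature neuron genes (0.517), thalamus markers (0.652), the DNA methylation machinery (0.858) and proliferation genes (0.902). Median, mean and test differed in sign for the lists of dentate granule cell, GABA receptor, glutamate receptor, DNA methylation, proliferation and immature neuron genes.

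**Figure D2:**
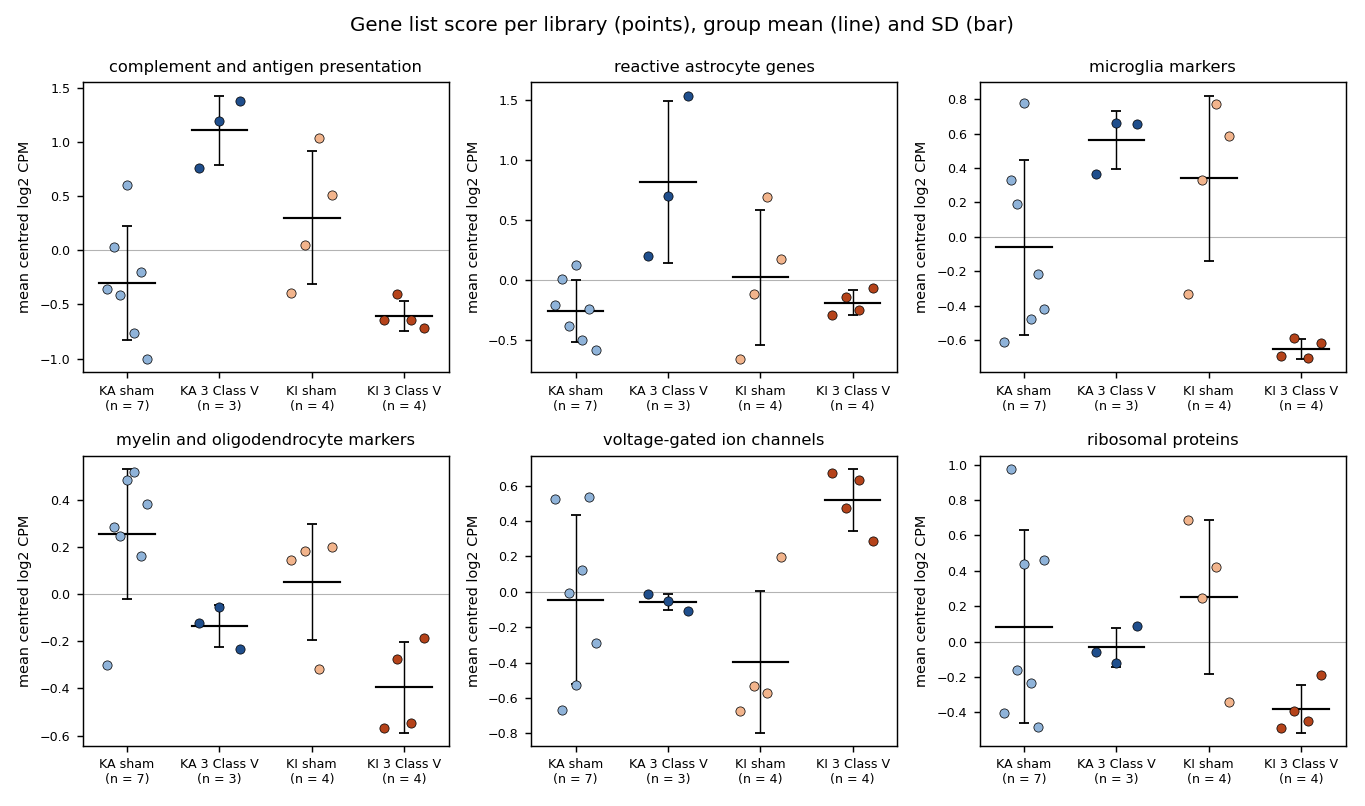
Score of 6 gene lists in each library (points), with the group mean (line) and SD (bar), as mean log2 CPM centred on each gene's mean over all libraries. The KI 3 Class V libraries lie at −0.71 to −0.59 for microglia markers and −0.49 to −0.19 for ribosomal proteins, and 3 of the 4 KI shams lie between −0.67 and −0.53 for voltage-gated channels.

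In the KI model, lists of microglial and antigen presentation genes were lower in 3 Class V than in sham, and lists of ion channels and neurotransmitter receptors were higher. Camera called these lists at the preset correlation but none with an estimated one (adjusted p = 0.537 for each). By fry the adjusted p was 0.0242 for microglia markers, voltage-gated channels and glutamate receptors. It was 0.0468 for activated microglia genes, 0.0176 for GABA receptors and 0.054 for complement and antigen presentation genes. Of the other lists that camera called in KI, cholesterol genes passed by fry (0.0111), and the rest lay at 0.054 to 0.327. Of 19 complement and antigen presentation genes 7 fell, and without KI sham 3 and 4 that list was at −0.48 and not called (camera adjusted p = 0.148). The voltage-gated channel list was at 0.82, and at 0.33 with the ribosomal protein covariate. Spp1 fell by 4.08 ± 1.04 in log2, Cd68 of macrophage lysosomes by 2.55 ± 0.66, the microglial receptor Trem2 by 1.78 ± 0.39 and its adaptor Tyrobp by 1.97 ± 0.45 (SE, n = 4 against n = 4, edgeR adjusted p from 0.0267 to 0.0333). The potassium channel gene Kcnq3 rose by 1.47 ± 0.32, the GABA receptor gene Gabra2 by 1.13 ± 0.26, and the glutamate receptor gene Gria3 by 1.03 ± 0.26 (edgeR adjusted p from 0.0266 to 0.0326). Mmp9, a matrix-degrading protease, rose from 4.95 ± 1.45 to 39.5 ± 7.89 CPM, 3.00 ± 0.65 in log2 (edgeR adjusted p = 0.0247). Plk5, a kinase gene, fell from 12.9 ± 9.33 to 2.25 ± 0.515 CPM, a log2 change of −2.52 ± 0.43 (edgeR adjusted p = 0.0185). The change was −1.88 for Plk5 without KI sham 1, −3.31 for Spp1 without KI sham 3 (edgeR adjusted p = 0.0774) and −1.79 for Cd68 without KI sham 4.

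By the rule for named genes, the largest rises after Mmp9 were in Acvr1c, an activin receptor (2.43 ± 0.68), the dopamine receptor Drd5 (2.27 ± 0.48), the serotonin receptor Htr2a (1.95 ± 0.47), St6gal2 (1.92 ± 0.49), the prostaglandin synthase Ptgs2 (1.77 ± 0.52), Fras1 (1.72 ± 0.43) and Hs6st3 (1.61 ± 0.48). The largest falls were in the imprinted RNA H19 (−3.42 ± 0.71), Fcrl2 (−3.02 ± 0.74), Sncg, which encodes a synuclein (−2.81 ± 0.75), the potassium channel gene Kcnn4 (−2.70 ± 0.63), the Fc receptor Fcgr3a (−2.59 ± 0.72), the coagulation factor F10 (−2.56 ± 0.63), Ifitm1 (−2.52 ± 0.58) and Plk5. Their edgeR adjusted p ran from 0.0185 to 0.0448. Fcgr3a stood at 25.4 ± 29.4 CPM in the KI shams and 4.22 ± 0.380 CPM in KI 3 Class V, the SD of the shams exceeding their mean. Without KI sham 3 the log2 change was −1.36 for Fcgr3a and −1.61 for F10, and without KI sham 1 it was −1.88 for Plk5. Of the 16 genes 7 lost the call without KI sham 3 and 4, with H19 at −1.75, Fcrl2 at −1.77, Sncg at −2.14, Kcnn4 at −1.22, Fcgr3a at −1.03, F10 at −1.23 and Ifitm1 at −0.87. Acvr1c was then at 3.39, St6gal2 at 2.61, Fras1 at 2.57 and Hs6st3 at 2.67. With the ribosomal protein covariate 15 of the 16 lost the call, with Mmp9 at 1.97 (edgeR adjusted p = 0.0908), and H19 kept it.

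Across all genes, 632 rose and 700 fell in KI 3 Class V, with a median fold of 1.74 in either direction. In 1139 of the 1332, every library of 1 group lay apart from every library of the other. With upper quartile factors the split was 333 up and 978 down, with the median of all genes at −0.103 in place of −0.0401, and with ribosomal RNA-like genes removed it was 426 up and 761 down. It was 1956 up and 1784 down without KI sham 3 and 4, and 1560 up and 1405 down by DESeq2. The count moved with single libraries. It was 9 without KI 3 Class V 1, 9 without 2, 9 without 3, 527 without 4, 454 without KI sham 2, 133 without KI sham 3 and 4297 without KI sham 4. It was 854 without KA 3 Class V 2, 838 without KA sham 3 and 2445 without KA sham 2. Without the 3 libraries rich in ribosomal RNA-like reads it was 17, with the ribosomal protein score as a covariate 105, and by DESeq2 2965. All 16 genes of the rule above lost the call without KI 3 Class V 1, 2 or 3 (edgeR adjusted p from 0.0541 to 0.118). Of them 9 lost it without KI 3 Class V 4 (up to 0.0639), 12 without KI sham 3 (up to 0.135), 5 without KI sham 2 (up to 0.0916) and 2 without KI sham 1 (up to 0.0716). Of 50 called genes taken from the lists and the overlap, 49 lost the call without each of KI 3 Class V 1, 2 and 3. Numbers lost were 27 without KI 3 Class V 4, 14, 25 and 39 without KI sham 1, 2 and 3, 10, 13 and 6 without KA 3 Class V 1, 2 and 3, and 11, 4, 7 and 7 without KA sham 3, 4, 5 and 7. The cholesterol biosynthesis gene Sc5d kept it without each library (edgeR adjusted p at most 0.0282).

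Microglia markers had negative fold changes in all 17 measured members (mean −1.09). Of these, 10 fell, among them Trem2, Tyrobp and Tmem119 (−0.70 ± 0.16), and 13 did so when adjusted over the list alone (camera adjusted p = 5.71e-07, and adjusted p = 0.537 with an estimated correlation). Of 18 activated microglia and macrophage genes 13 fell, with Apoe at −0.97 ± 0.18, and 14 when adjusted over the list alone (mean −1.58; camera adjusted p = 7.38e-05, and adjusted p = 0.537 with an estimated correlation). Of 19 complement and antigen presentation genes 7 fell, with the immunoproteasome subunits Psmb8 at −1.40 ± 0.33 and Psmb9 at −1.64 ± 0.45, and 12 when adjusted over the list alone (mean −1.03; camera adjusted p = 1.79e-05, and adjusted p = 0.537 with an estimated correlation). Without KI sham 3, Psmb9 was at −0.87 (edgeR adjusted p = 0.123). Of 19 cytokines and chemokines 3 fell (Il18, Cxcl16 and Tgfb1 at −1.60 ± 0.39, −1.72 ± 0.45 and −1.10 ± 0.31) and Ptgs2 rose. Adjusted over the list alone, 10 fell and 1 rose (mean −1.39; camera adjusted p = 0.00142, and adjusted p = 0.592 with an estimated correlation). The score of the activated list was 1.28 in KI sham 3, 1.16 in KI sham 4, 0.05 in KI sham 2 and −0.91 in KI sham 1, against −0.90 to −0.62 in KI 3 Class V. Without KI sham 3 and 4 the mean change was −0.74 for microglia markers (camera adjusted p = 0.0140), −0.50 for activated genes (0.292), −0.48 for complement genes (0.148) and −0.34 for cytokines (0.531). The cytokine list was at −0.86 with the ribosomal protein covariate, and without KI sham 3 alone the cytokine list was at −0.58 (0.0624).

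Channel and receptor genes were higher in KI 3 Class V. Of 24 voltage-gated channel genes 6 rose, with the calcium channel genes Cacna1h at 0.79 ± 0.20 and Cacna1g at 1.27 ± 0.32, and 17 when adjusted over the list alone (mean 0.82; camera adjusted p = 2.50e-07, and adjusted p = 0.537 with an estimated correlation). Of 22 glutamate receptor genes 2 rose, Gria3 and Gria1 (0.94 ± 0.28), and 8 when adjusted over the list alone (mean 0.64; camera adjusted p = 1.79e-05, and adjusted p = 0.537 with an estimated correlation). Of 16 GABA receptor and chloride transporter genes 4 rose and Gabrd, the subunit of extrasynaptic receptors, fell (−0.80 ± 0.22). Adjusted over the list alone, 10 rose and 1 fell (mean 0.67; camera adjusted p = 0.000110, and adjusted p = 0.537 with an estimated correlation). Among 15 interneuron markers Gad2, which makes GABA, rose (1.58 ± 0.42), and 5 rose and 1 fell when adjusted over the list alone (mean 0.44; camera adjusted p = 0.0115, and adjusted p = 0.556 with an estimated correlation). Cholesterol biosynthesis genes were higher by a mean of 0.35. Of the 19, 4 rose, with Sc5d at 0.62 ± 0.09 and Hmgcs1 at 0.46 ± 0.10, and 10 when adjusted over the list alone (camera adjusted p = 0.000110, and adjusted p = 0.537 with an estimated correlation). Complex I subunits were lower by a mean log2 change of −0.52, with 1 of 28 falling (Ndufs7 at −0.64 ± 0.20) and 0 when adjusted over the list alone (camera adjusted p = 0.000303, and adjusted p = 0.662 with an estimated correlation). The ribosomal protein score was −0.49 to −0.19 in KI 3 Class V, −0.34 in KI sham 4 and 0.24 to 0.69 in the other KI shams. With it as a covariate the voltage-gated list stood at 0.33 (camera adjusted p = 0.000115), glutamate receptors at 0.24 (0.00901), GABA receptors at 0.35 (0.00135), interneuron markers at 0.16 (0.110) and complex I at 0.08 (0.0549). With 1 surrogate variable these means were 0.45, 0.34, 0.42, 0.25 and 0.018. Complex I was at −0.29 without KI sham 1 and −0.82 without KI sham 3 and 4. Without KI sham 3 and 4 the call ended for interneuron markers (mean 0.60, camera adjusted p = 0.0957) and cholesterol genes (mean 0.25, camera adjusted p = 0.168).

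Oligodendrocyte genes were lower in KI as well. Of 15 myelin and oligodendrocyte markers 4 fell, with Cnp at −0.74 ± 0.18, Nkx6-2 at −0.81 ± 0.20 and Cldn11 at −0.82 ± 0.21, and 8 when adjusted over the list alone (mean −0.47; camera adjusted p = 0.000552, and adjusted p = 0.537 with an estimated correlation). Of 14 proliferation genes Mcm5 (−1.29 ± 0.39) and Birc5 (−0.80 ± 0.25) fell, also when adjusted over the list alone (mean −0.49; camera adjusted p = 0.0382, and adjusted p = 0.656 with an estimated correlation). That list stood at −0.27 without KI sham 4 (camera adjusted p = 0.547), −0.44 without KI sham 3 (0.0639) and −0.41 without KI 3 Class V 4 (0.142), and at 0.01 without KI sham 3 and 4 together. Choroid plexus markers had a mean of −3.02, with 0 of 12 passing and 11 when adjusted over the list alone (camera adjusted p = 0.0445, and adjusted p = 0.662 with an estimated correlation), but a mean of −0.30 without KI sham 4 (camera adjusted p = 0.962), the library rich in Ttr. That list was also not called without any 1 of KA 3 Class V 1 to 3, KA sham 2, 4, 5, 6 and 7, and KI 3 Class V 1 to 3, with camera adjusted p from 0.0504 to 0.0863. The lists of immediate early genes (camera adjusted p = 0.454), heat shock and stress genes (0.0799), reactive astrocyte genes (0.161), astrocyte markers (0.515), oligodendrocyte precursors (0.219) and matrix genes (0.751) were not called in KI; for matrix genes the median and mean were negative and the test pointed up. Within them Fos fell (−0.82 ± 0.20), as did Ier2 (−0.66 ± 0.15), Cdkn1a (−1.21 ± 0.22), Mt1 (−1.30 ± 0.34) and Neu4 (−0.95 ± 0.20), while Mmp3 (2.84 ± 0.81, and 3.52 without KI sham 3) and Aqp4 (0.61 ± 0.19) rose. Trh stood at 24.0 ± 10.4 CPM against 3.31 ± 0.876 CPM in the KI shams (2.86 ± 0.99, edgeR adjusted p = 0.0633), in a neuropeptide list that was not called (camera adjusted p = 0.205). Also not called were markers of endothelium and pericytes (0.745), dentate granule cells (0.155), pyramidal cells (0.420), thalamus (0.317) and blood (0.0802), immature neuron genes (0.590) and the DNA methylation machinery (0.0987). Camera called some of these without 1 library. Without KI sham 1 these were neuropeptides (0.0312), reactive astrocyte genes (0.00622) and thalamus markers (0.0484). Without KI sham 2 they were stress genes (0.0385) and blood genes (0.0282), the latter also without KA sham 1 (0.0475) or KI 3 Class V 4 (0.0405). Camera also called the DNA methylation machinery without KI sham 3 and 4 (0.0184), and with the ribosomal protein covariate oligodendrocyte precursors (0.000385), thalamus (0.000854), matrix (0.00235) and endothelial markers (0.00975), these 4 lower.

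The change differed between the models for 507 genes, with a positive KA minus KI difference in 420 and a negative one in 87. This balance turned without KI sham 3 and 4, with 253 positive and 398 negative of 651, and by limma-voom, with 2232 positive and 2538 negative. The difference, KA minus KI in log2, was 4.56 ± 1.13 for the phagocyte receptor Clec7a, 4.43 ± 0.92 for the zinc transporter Slc39a12, 4.38 ± 0.57 for RT1-Ba, 4.37 ± 1.10 for the proteoglycan Sdc1 and 4.13 ± 0.54 for Cd74 (edgeR adjusted p from 0.00158 to 0.0356). On the other side it was −1.93 ± 0.53 for the receptor tyrosine kinase Met, −1.92 ± 0.46 for Ndst4, −1.81 ± 0.49 for Ndst3, −1.77 ± 0.48 for Zdhhc23 and −1.60 ± 0.42 for Slc35d3 (edgeR adjusted p from 0.0297 to 0.0498). Ndst3 and Ndst4 encode enzymes of heparan sulfate synthesis. Of the 23 genes that rose in KA, 21 had negative KI fold changes, with a median of −0.60, and 21 differed between the models. The named genes other than RT1-Ba and Cd74 lost the call in part without each library except KA sham 2, KA sham 4 and KI sham 1. That held for 8 of them without KI 3 Class V 1 or 3, 7 without KI 3 Class V 2, KA 3 Class V 2 or 3, or KI sham 3, and 1 to 6 otherwise. Their edgeR adjusted p was then at most 0.391 (Sdc1 without KA 3 Class V 3, where its difference was 1.48). Without KA 3 Class V 2 the difference was 2.87 for Slc39a12, and without KI sham 3 it was 3.63 for Clec7a and 3.52 for Sdc1. With KI sham 3 and 4 both left out it was 2.02 for Clec7a, 2.26 for Slc39a12 and 2.49 for Sdc1, none of them called (edgeR adjusted p = 0.193, 0.0784 and 0.156), and −2.49 for Ndst3. The count was 410, 152 and 56 without KA 3 Class V 1, 2 and 3, and 332, 768, 336, 777, 330, 329 and 334 without KA sham 1 to 7. It was 128, 203, 131 and 264 without KI 3 Class V 1 to 4, and 897, 439, 205 and 697 without KI sham 1 to 4.

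The KA minus KI difference was positive for inflammatory lists and negative for channel and receptor lists. Complement and antigen presentation genes differed by a mean of 2.33 (11 of 19 members called, and 19 when adjusted over the list alone, camera adjusted p = 5.63e-18, and adjusted p = 0.177 with an estimated correlation). Microglia markers differed by 1.62 (11 of 17 called, 14 when adjusted over the list alone, camera adjusted p = 1.92e-12, and adjusted p = 0.177 with an estimated correlation), and reactive astrocyte genes also by 1.62 (6 of 20 and 14 when adjusted over the list alone, camera adjusted p = 8.23e-09, and adjusted p = 0.177 with an estimated correlation). Activated microglia genes differed by 2.15 (8 of 18 and 14 when adjusted over the list alone, camera adjusted p = 1.94e-08, and adjusted p = 0.210 with an estimated correlation) and cytokines by 2.22, or 1.41 without KI sham 3 (5 of 19 and 13 when adjusted over the list alone, camera adjusted p = 2.98e-07, and adjusted p = 0.252 with an estimated correlation). The difference was 1.07 for activated microglia genes, 1.17 for cytokines and 1.07 for reactive astrocyte genes without KI sham 3 and 4, each still called. Stress genes differed by 0.75 (2 of 18 and 7 when adjusted over the list alone, camera adjusted p = 0.000566, and adjusted p = 0.177 with an estimated correlation). Immediate early genes differed by 0.54 (3 of 18, and 4 up with 1 down when adjusted over the list alone, camera adjusted p = 0.00961, and adjusted p = 0.331 with an estimated correlation), but by 0.28 without KA 3 Class V 3 (camera adjusted p = 0.110). Cholesterol genes differed by −0.51 (3 of 19 and 9 when adjusted over the list alone, camera adjusted p = 4.56e-07, and adjusted p = 0.177 with an estimated correlation). With 0 members called by either count, voltage-gated channels differed by −0.90 (camera adjusted p = 1.67e-07, and adjusted p = 0.331 with an estimated correlation), and GABA receptors by −0.69 (camera adjusted p = 0.000165, and adjusted p = 0.252 with an estimated correlation). So did glutamate receptors by −0.64 (camera adjusted p = 0.000140, and adjusted p = 0.331 with an estimated correlation) and interneuron markers by −0.54 (camera adjusted p = 0.00626, and adjusted p = 0.371 with an estimated correlation). Pyramidal cell markers differed by −0.43 (camera adjusted p = 0.00894, and adjusted p = 0.248 with an estimated correlation), and by −0.38 without KI sham 3 and 4, where the list was not called (0.113). With the ribosomal protein covariate the difference was −0.44 for voltage-gated channels, −0.39 for GABA receptors, −0.26 for glutamate receptors and −0.26 for interneuron markers, the last no longer called (camera adjusted p = 0.0739). Myelin markers had negative means in both models, and no difference between them was called (mean 0.05, camera adjusted p = 0.579), which does not show that the changes were equal. The other 13 lists were not called, with camera adjusted p from 0.0522 for proliferation genes to 0.808 for neuropeptides, whose mean was positive while median and test were negative. By camera, proliferation genes were called without KA 3 Class V 1, KA sham 2, 3 or 4, KI 3 Class V 1, 2 or 3, or KI sham 1 or 2 (0.00303 to 0.0482). Choroid plexus markers were called without KA sham 3 (0.0311), KI sham 1 (0.0436) or KI sham 3 (0.0493). Without KI sham 1 matrix (0.0436) and thalamus genes (0.0416) were called, and without KI sham 4 complex I (0.00546) and DNA methylation genes (0.0479). Complex I and DNA methylation genes were also called without KI sham 3 and 4 (0.00144 and 0.00766). With the ribosomal protein covariate camera called matrix (mean 0.93, 0.000585), endothelial (mean 0.34, 0.00649) and thalamus genes (0.00821). It then also called proliferation (0.0220), choroid plexus (0.0230) and oligodendrocyte precursor genes (0.0329), and complex I in the other direction (mean −0.29).

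RT1-Db1, Fos and Ciita, the activator of class II genes, were called higher in KA and lower in KI, but none kept the KI call without each library. The log2 changes were 2.73 ± 0.28 and −1.08 ± 0.31 for RT1-Db1, 1.34 ± 0.18 and −0.82 ± 0.20 for Fos, and 2.21 ± 0.37 and −1.62 ± 0.44 for Ciita. The KI call ended without any 1 of the KI 3 Class V libraries or KI sham 3 for all 3 genes, and for RT1-Db1 also without KI sham 2 or KA 3 Class V 2 (edgeR adjusted p up to 0.117). The KA call of Ciita ended without KA 3 Class V 2 (edgeR adjusted p = 0.0772) or 3 (0.179), and its KI libraries overlapped between the groups (0.404 ± 0.110 against 1.24 ± 0.788 CPM). Across the models 1 gene was called in the same direction, where independent lists of these sizes would share 1.09 rising genes (Fisher's exact test, two-sided, p = 1). Across all genes tested the fold changes of the models had Pearson r = 0.03 and Spearman rho = 0.13, and genes are not independent replicates. By edgeR 0 genes were shared without KI 3 Class V 1, 2 or 3. Without KA sham 1 the shared genes numbered 16 rather than 1, and 2 without KI sham 1 or KI sham 4. DESeq2 gave 15 with all libraries, and limma-voom 116.

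**Figure D3:**
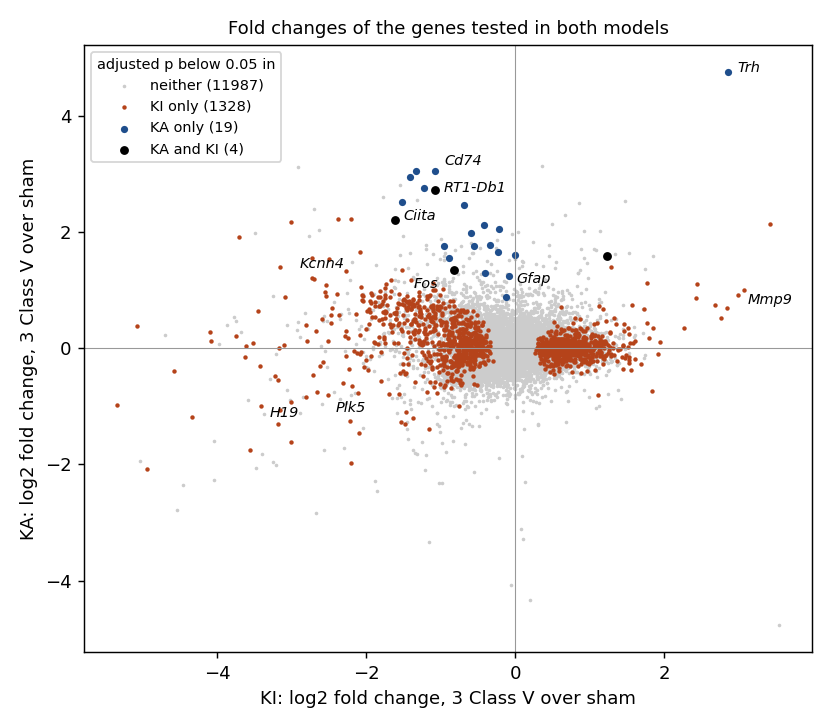
Log2 fold change of each tested gene in KI (x axis) and KA (y axis), coloured by the comparisons in which its edgeR adjusted p was below 0.05. Most genes that rose in KA lie left of 0 on the KI axis, among them RT1-Db1, Fos and Ciita, which were called in both models.

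The shams of the models differed in 1 gene by edgeR. Polr3k, a subunit of RNA polymerase III, was at 99.1 ± 11.5 CPM in the KI shams and 53.9 ± 4.19 CPM in the KA shams, a log2 difference of −0.88 ± 0.10 (edgeR adjusted p = 0.00160). The KI shams held 89.3 to 113 CPM of it and the other 14 libraries 48.9 to 71.1 CPM. As groups, complement and antigen presentation genes were lower in the KA shams than in the KI shams by a mean log2 difference of −0.60 (camera adjusted p = 2.95e-07, and adjusted p = 0.689 with an estimated correlation) and cholesterol genes were higher by 0.25 (camera adjusted p = 3.59e-06, and adjusted p = 0.376 with an estimated correlation). Model and any handling batch coincide in this comparison and the labels give no batch. The library numbers in the labels run from 1 to 6 in the KI shams and from 13 to 17 in KI 3 Class V. They run from 18 to 24 in the KA shams and from 32 to 35 in KA 3 Class V. A batch that follows these numbers therefore cannot be told from the change within either model. Between the shams, leaving out KA sham 1 or KI sham 1 gave 2 genes and leaving out KI sham 2 gave 3. Without KI sham 3 and 4 together the count was 625. DESeq2 called 11 genes between the shams and limma-voom 411. Camera also called lower lists of microglia markers (−0.38, adjusted p = 0.000249), stress (−0.31, 0.00236), reactive astrocyte (−0.44, 0.00236), activated microglia (−0.66, 0.00396) and cytokine genes (−0.50, 0.0103) in the KA shams. It called higher lists of voltage-gated channels (0.33, 0.000880), GABA receptors (0.28, 0.00431), glutamate receptors (0.24, 0.0128), astrocyte (0.19, 0.0103), interneuron (0.27, 0.0119) and myelin markers (0.20, 0.0275). With an estimated correlation the adjusted p was 0.376 for stress genes and 0.689 for the other 10 of these. In 323 of the 1332 genes called in KI, the KI shams lay farther from the KA shams than the KI 3 Class V libraries did.

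**Figure D4:**
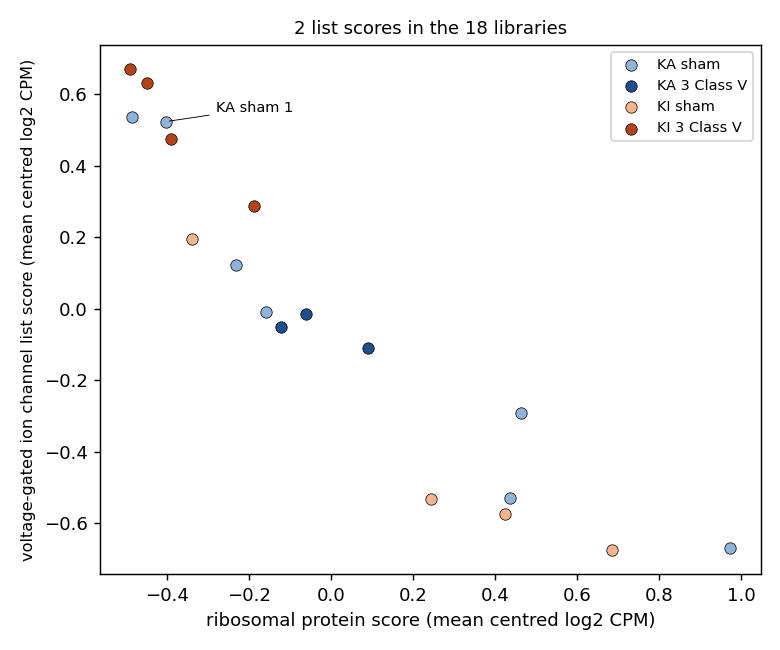
Score of the voltage-gated channel list (y axis) against the score of 88 ribosomal protein genes (x axis) in the 18 libraries, coloured by group. Within the 7 KA shams the 2 scores had Pearson r = −0.95, and KA sham 1 is marked.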

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

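The tests of a wrong label for KA sham 1 and of KI sham 3 and 4 were chosen after the results were seen, and those with the ribosomal protein score or without choroid-rich libraries were added after the data were seen.

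In 24 of 240 tests of single groups, 1 library lay far from the others of its group, and chance marks about 1 in 20 groups. The tests cover 48 genes, 27 lists and 5 measures of the libraries in the KA shams, KI 3 Class V and the KI shams. KA 3 Class V (n = 3) was not tested for outlying libraries. KA sham 1 had the lowest Plk5 of the KA shams (3.18 CPM, others 9.03 to 12.2) and the highest neuropeptide score (0.38, others −0.35 to −0.19). KA sham 2 was low in Slc35d3 (1.13 CPM, others 2.74 to 4.42). KA sham 3 was high in choroid plexus markers (2.89, others −0.82 to 0.32), and KA sham 4 in ribosomal RNA-like reads (9.81%, others 0.587% to 2.04%). Such reads were also high in KI 3 Class V 1 (16.6%, others 0.790% to 1.01%) and KI sham 2 (16.7%, others 0.665% to 0.801%). KI 3 Class V 4 was low in Fcrl2 (1.28 CPM, others 3.31 to 3.68), Ifitm1 (0.898 CPM, others 1.65 to 1.83) and Plk5 (1.49 CPM, others 2.43 to 2.63). The same library was high in S1pr3 (25.6 CPM, others 19.7 to 20.6), Pla2g7 (54.5 CPM, others 37.3 to 39.7) and Gfap (4499 CPM, others 3101 to 3302). Its list scores stood apart for neuropeptides (0.16, others 0.27 to 0.29), GABA receptors (0.25, others 0.46 to 0.50), astrocyte markers (0.11, others −0.08), oligodendrocyte precursors (−0.040, others −0.19 to −0.16) and choroid plexus markers (−0.091, others −1.05 to −0.91). KI 3 Class V 2 was high in Fcgr3a (4.78 CPM, others 3.97 to 4.09). KI sham 1 was low in RT1-Ba (4.53 CPM, others 8.83 to 10.1), Drd5 (0.450 CPM, others 1.60 to 1.82) and St6gal2 (0.208 CPM, others 2.74 to 3.93). KI sham 3 was low in myelin markers (−0.32, others 0.14 to 0.20) and KI sham 4 high in voltage-gated channels (0.20, others −0.67 to −0.53).

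A test of the KA change minus the KI change passed for 32 of the 48 genes, given here in log2. The count largely follows from how the genes were selected: it was 29 of the 31 picked for that difference or called in KA, and 3 of the 17 picked for KI or the shams. Antigen presentation genes and their activator had differences of 4.13 (Cd74), 4.38 (RT1-Ba), 3.81 (RT1-Db1), 4.05 (RT1-Da), 3.99 (RT1-Db2) and 3.83 (Ciita). Glial and complement genes had 2.71 (C3), 2.32 (Serping1), 1.33 (Gfap), 2.58 (Aspg), 1.60 (S1pr3), 2.54 (Hspb1), 4.56 (Clec7a), 1.69 (Pla2g7) and 1.89 (Bag3). Activity-dependent genes had 2.16 (Fos) and 2.45 (Egr2). Channel and transporter genes had 3.16 (Scn7a), 3.89 (Kcnn4), 2.28 (Lrrc8e) and 4.43 (Slc39a12). Others were 3.53 (F10), 4.37 (Sdc1), 4.36 (Acoxl), 2.12 (Fgfbp1), 1.89 (Bag3), 1.002 (Mmp11) and 1.01 (Polr3k). Negative differences were −1.93 (Met), −1.92 (Ndst4), −1.81 (Ndst3), −1.77 (Zdhhc23) and −1.60 (Slc35d3).

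By camera at the preset correlation the same difference passed for 13 lists. None of them passed with an estimated correlation (camera adjusted p from 0.177 to 0.371). By fry they passed (adjusted p from 0.00453 to 0.0414) except voltage-gated channels (0.0607), glutamate receptors (0.0804) and interneuron markers (0.0923). Mean differences were 2.33 for complement and antigen presentation, 2.22 for cytokines, 2.15 for activated microglia, 1.62 for microglia markers and for reactive astrocyte genes, 0.75 for stress genes and 0.54 for immediate early genes. They were −0.90 for voltage-gated channels, −0.69 for GABA receptors, −0.64 for glutamate receptors, −0.54 for interneuron markers, −0.51 for cholesterol biosynthesis and −0.43 for pyramidal cell markers.

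Counts of called genes were set against those from other splits of the same libraries. Such splits cannot separate a change from a batch that follows the groups. In KI, 1 of 35 splits, the real one, gave as many (1332 genes, highest other 0), so chance is excluded at 0.05. In KA, 3 of 100 splits, the real one among them, gave 23 genes or more. That share is under 0.05, but not every possible split was drawn, so chance is not firmly excluded. The highest other gave 3509, which points to a structure of the samples other than the groups. That split set apart KA sham 2, 4 and 7, the 3 KA libraries with the highest ribosomal protein scores (0.974, 0.437 and 0.464). The other KA libraries lay at −0.485 to 0.0898. For the difference between the models, 1 of 100 relabellings, the real one, gave 507 genes (highest other 144). These relabellings broke up the groups of both models at once. They exclude chance at 0.05 only if neither model changed, and cannot exclude it for a change that was equal in both. For genes shared by the models 1 of 100 relabellings, the real one, gave 1 gene (highest other 0). In 0 of the 99 others did both models have called genes, so none could be shared and this comparison decides nothing. The 1 shared gene is what independent lists would give (1.09 expected, Fisher p = 1). For the correlation of fold changes 91 of 100 relabellings gave a value as large (0.03, highest other 0.54), and for the shams 8 of 100 splits gave 1 gene or more (highest other 4188), so chance is not excluded for either.

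KA sham 1 lay closest to the KI 3 Class V libraries, with 41.4 CPM of Mmp9 and 23.7 CPM of Trh. After regression on the ribosomal protein score its residuals still correlated more with KI 3 Class V than with the other KA shams, by 0.359. Whether that score is the whole cause is not settled, since part of the gap may follow from how KA sham 1 was picked. Its deviation from the other KA shams followed the KI fold change with a slope of 0.647 over 759 genes (other KA shams −0.56 to 0.31), but this library was picked for its likeness to KI 3 Class V, so the slope restates that likeness, and a wrong label stays open. Each KI 3 Class V library correlated more with its own group (mean r = 0.991 to 0.994) than with the other KA shams (0.974 to 0.980), so none looks like a KA sham exchanged for it, while a single wrong label or a sample from outside the series needs no such partner. The labels number KA sham 1 as 18, between the KI 3 Class V libraries (13, 14, 16 and 17) and the other KA shams (19 to 24), which decides nothing; a KA sham animal that differed from the others, or a batch, which the labels do not give, stays open and was not tested.

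The channel and receptor lists were higher in KI 3 Class V, and in the 7 KA shams the voltage-gated list fell along the ribosomal protein score (r = −0.95, exact p = 0.000595, Benjamini-Hochberg adjusted p = 0.000794 over 4 relations, r = −0.97 without the 2 farthest libraries). That score may carry part of the KI change, since with it as a covariate 0.405 of the main value was left (mean 0.33 against 0.82). The slope within the KA shams would give a KI change in score of 0.53 where 0.91 was observed, so a part beyond it stays open. Without KA sham 1 the slope would give 0.49, and in those 6 KA shams r was −0.95 (exact p = 0.0111). RNA quality, dissection or an effect of kindling on neurons could each move both scores, and the covariate overlaps the groups.

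The activated microglia list was lower in KI 3 Class V, and KI sham 3 and 4 held its highest values. Without these 2 libraries 0.316 of the change was left (mean −0.50, camera adjusted p = 0.292) with 2 shams to compare, so a high level in these 2 libraries and a fall in KI 3 Class V cannot be told apart. For microglia markers 0.679 of the change was left and the list was still called, which argues against these 2 libraries as the whole cause there. Choroid plexus tissue in the dissection was argued against, since 0.890 of the change was left without the 2 libraries rich in its transcripts. A lower microglial level after kindling stays among the open explanations, as does inflammation around the electrode in some shams, which was not tested.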

How the results depend on the processing

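Alternatives on ribosomal RNA-like reads and genes, the ribosomal protein covariate, choroid plexus transcripts, KI sham 3 and 4, and KA sham 1 with the covariate were chosen after seeing the data; the others were planned. Where a cause is not given, the cause was not tested. DESeq2 called 254 genes in KA, 2965 in KI, 1117 between the models, 15 shared and 11 between the shams, and limma-voom called 725, 7355, 4770, 116 and 411, against 23, 1332, 507, 1 and 1 by edgeR. At adjusted p below 0.1 edgeR called 71 in KA, 3518 in KI, 965 between the models and 6 shared, as a looser threshold must call more. Fitting each model alone gave 759 in KI, with fewer residual degrees of freedom. With the replicate number as a replicate block the counts were 3 in KA, 0 in KI (where 4728 genes had an unadjusted p under 0.05 without the block), 11 between the models and 0 shared. Within each model, deviations from the group mean were correlated between sham and 3 Class V libraries of the same number. These correlations were −0.15 to 0.01 in KA and −0.17 to −0.07 in KI, so the numbers showed no pairing of the samples. The block also ended the calls of astrocyte markers (camera adjusted p = 0.267) and cholesterol genes (0.0505) in KA. With 1 surrogate variable the counts were 87 in KA, 647 in KI, 1397 between the models and 6 between the shams. With the ribosomal protein covariate they were 205, 105, 1025 and 6, with 2 shared, and also without KA sham 1 they were 181, 389, 848 and 3, with 15 shared. Without the libraries rich in ribosomal RNA-like reads KI had 17 genes, 0 were shared and 0 differed between the shams. Without those rich in choroid plexus transcripts KI had 3937 and 2 were shared. Without KI sham 3 and 4 the counts were 69 in KA, 3740 in KI, 651 between the models, 9 shared and 625 between the shams. Leaving out each library in turn gave 9 to 110 genes in KA, 9 to 4297 in KI, 56 to 897 between the models, 0 to 16 shared and 1 to 3 between the shams. The correlation of fold changes ran from −0.18 with the surrogate variable to 0.20 without KA 3 Class V 3, and from −0.12 to 0.20 over single libraries left out. Over KA, KI and their difference, the gene list tests called 40 of 81, 0 with an estimated correlation, 21 by fry and 35 to 47 over single libraries left out. In KI the test of the matrix list turned from up to down, while its mean, −0.012 at first, went to −0.36 with the surrogate variable, −0.46 with the covariate and −0.38 with the covariate and without KA sham 1. The endothelial list reversed to −0.20, −0.25 and −0.25. Complex I in KI reversed to 0.018, 0.084 and 0.10 under the same 3, and its difference between the models to −0.29 with the covariate and −0.29 also without KA sham 1. Proliferation genes in KI reversed to 0.011 without KI sham 3 and 4. Of 1210 other comparisons for single genes 894 kept their call, 316 lost it and 0 reversed, and of 2592 for lists 2402 were the same, 109 lost the call, 69 gained it and 12 reversed, as given above. At the depth of these libraries 13338 of 17455 genes were tested, and depth itself was not varied. With no filter on low counts KA had 27 genes and KI 1218, and with a stricter one 17 and 1267.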

Other observations

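The genes below were chosen after their values were seen, and the test with the ribosomal protein covariate was added after the data were seen, its relabellings and its repeat without KA sham 1 after its result.

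Without KA sham 1, 16 genes were called the same way in both models, 7 up against 2.65 expected and 9 down against 0.781 expected. Among the rising genes were Trh (KA 5.96, KI 2.84 in log2), the complexin Cplx4 (3.78, 3.41), Mmp9 (1.72, 2.98), Cdh23 (1.36, 0.96), the neurokinin B gene Tac3 (1.28, 1.10) and Dgka (0.41, 0.60). Among the falling genes were Pnlip (−1.47, −1.49) and Tmem163 (−0.88, −1.20). Omission of any other 1 of the KA shams left 1 shared gene. KA sham 1 was singled out for its likeness to KI 3 Class V, so leaving it out moves the KA changes toward the KI changes by construction.

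A common change of the models hidden by the ribosomal protein score was tested and not seen, but the test does not settle it. The correlation of their fold changes was −0.16 with that score as a covariate and 0.03 without it, and lay below the bound of 0.1 set beforehand by more than its SD (0.195 over 99 relabellings with the covariate, of which 41 were as far from 0). Without KA sham 1 it was −0.048, below the bound by less than that SD, which decides nothing. The relabelled values with the covariate ran from −0.49 to 0.52, so a modest common change cannot be told from none. A common change that the score does not hide was not excluded by this test.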
